A study of Homo sapiens with 2 samples.

How the data were processed

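Total RNA of HEK-293T cells was measured on 2 Affymetrix 3' expression arrays, 1 from cells given a miR-194 mimic and 1 from cells given a negative control mimic. Each mimic was used at 50 nM and the treatment lasted 48 h, per the labels. Groups were taken from the treatment named for each sample, and each group holds 1 array. No p-value between the conditions can be computed from 1 array per group, so differences were described by size, and the single array per group limits the precision of every value. Differences between the cultures, labelling reactions and arrays cannot be separated from an effect of the mimic.

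The deposited values are log2 signals, 1 per probe set and array. MAS5 is named in the submitters' processing notes, without a version, and the log base and the scaling target are not given in the sources used here. The base was checked on the values: raising 2 to each value gave a 2% trimmed mean of 500.1 on both arrays, as a common MAS5 scaling on a log2 scale would give. The deposited log2 columns had medians of 6.10 (control mimic) and 6.07 (miR-194 mimic), no value below 0, and 236 and 264 values of exactly 0. Each column is the signal of 1 array and not a ratio, so no direction had to be inferred. Detection calls were not used here. Of the array's control transcripts with 3' and 5' probe sets, 1 is not reported here and was left out of the summary over them. Scanner files were not analysed here, so background correction and probe summarisation are those of the authors.

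The table holds 54675 probe sets, of which 62 are array controls. The platform's gene annotation, which can be older than the gene names in use, names 1 gene for 41097 probe sets and several genes for 1801, and the latter were left out. Another 11777 probe sets are not listed in it and are unnamed here. Of the probe sets with 1 gene, 41043 matched a RefSeq gene of the GRCh38.p14 annotation through the Entrez identifier, and no symbol differed. Genomic gene lengths came from that annotation, and 99.9% of the genes analysed had one. No coordinates are printed, because only probe set names tie the values to the genome.

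Signals under an array's median over its non-control probe sets were set to that median, 6.10 and 6.06 on the log2 scale. A probe set was kept when the mean of its 2 floored signals lay above the mean floor, and each gene was represented by its kept probe set with the highest mean signal. This left 12769 genes, of which 11634 lay above the floor on both arrays. For the other 1135 genes the difference is a bound for that probe set, written as "at least". All differences are log2 signal with the miR-194 mimic minus log2 signal with the control mimic, on the authors' scaling. The median difference over the kept genes was 0.02.

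In place of a replicate error, the disagreement between probe sets of a gene was used. For the 6456 genes with 2 or more kept probe sets, the SD of the difference between the log2 differences of the 2 brightest probe sets, divided by the square root of 2, was 0.38 at low signal (mean log2 up to 9.23), 0.31 at middle signal (up to 10.87) and 0.27 at high signal. This value, called the probe set error, follows a gene's log2 difference after the ± sign where it is printed. It includes probes that read different isoforms and leaves out variation between cultures and between labelling reactions.

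Gene lists for pathways, cell type markers, control genes and genes that other studies reported as miR-194 targets were fixed before the data were examined. For each list the median log2 difference of its kept genes was set against the medians of 10000 random lists of the same size, drawn from the kept genes with the same number of genes in each of 10 classes of mean signal. The percentile describes these 2 arrays and is not a test of the conditions. Thresholds of 2-fold and 1.5-fold were used for counts, and a gene's difference and its place past a threshold refer to its brightest kept probe set.

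The named genes also followed a rule fixed before the data were examined. It takes the 12 largest differences in each direction among genes above the floor on both arrays whose 2 or more kept probe sets all differed the same way by 1.5-fold or more, then up to 2 genes per direction with the largest bound, up to 2 members per direction of each list, and every reported target past 1.5-fold. Genes on chromosome Y and XIST were left out of naming. The planned comparison of genes with and without miR-194 seed matches in their 3' UTR needs transcript sequence, which was not used here, so it was not run.

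Alternatives fixed before the data were examined were other scalings between the arrays (median, quantile, loess with a span of 0.3), other floors (the 25th and 75th percentiles, the 95th percentile of 135 olfactory receptor probe sets, and none), the mean over a gene's probe sets, leaving out probe sets designed on shared sequence (names ending in _s_at, _x_at or _a_at), a 1.5-fold threshold, agreement between probe sets, and random lists matched also on the number of probe sets. Matching on gene length and removal of the gene length trend were added after the data were seen.

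The scripts were tested on simulated data before use. With a noise SD of 0.2 per array and 200 changed genes, the 2-fold count recovered 98.0% of genes raised 3-fold and 85.4% of genes lowered 3-fold among 12431 kept genes, while 6 of 12235 unchanged genes passed. The simulated noise was the same at every signal and held no variation between cultures, whereas the probe set error of the data was larger at low signal. These shares therefore test the scripts and do not give the rate of false calls in the data. Of 100 random lists of 24 unchanged genes, 4 fell outside the central 95%, and 76 of 100 such lists lowered by 0.2 fell below the 2.5th percentile. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.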

Results

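Gene expression was measured in HEK-293T cells, an established line derived from human embryonic kidney that carries the SV40 large T antigen. Cells received synthetic miR-194, a microRNA known for its high level in liver and intestinal epithelium, or a negative control mimic. A mimic is a short RNA duplex that loads the cell's silencing complex as the natural microRNA would. Each group held 1 array with signals for 54675 probe sets, and 12769 genes passed the signal filter. The 2 arrays correlated with Pearson's r of 0.99 across these genes, which are not independent replicates. The comparison asks which transcripts differ 48 h after miR-194 is supplied.

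More genes were lower than higher with the miR-194 mimic. Of the 12769 genes, 181 (1.42%) were lower by 2-fold or more and 55 (0.43%) were higher, a ratio of 3.29. The ratio depended on the floor for low signals: it was 1.23 with no floor, 1.53 with a floor at the 25th percentile, 8.25 at the olfactory receptor level and 89.0 at the 75th percentile. At 1.5-fold the counts were 933 lower and 381 higher. The central 95% of all log2 differences ran from -0.87 to 0.62. The difference between the counts was not tested, because each group has 1 array. Of the genes past 2-fold, 117 of the 181 lower and 13 of the 55 higher had at least 2 kept probe sets. All of these probe sets differed in the gene's direction for 86 lower and 7 higher genes.

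Among the lower genes, CEP290, a protein of the ciliary transition zone, had the largest difference among genes with agreeing probe sets and signals above the floor on both arrays, a log2 difference of -2.24 ± 0.31, which is 4.71-fold. Its signal was 1342 with the control mimic and 285 with miR-194. ATRX, a chromatin remodeller, was lower at -1.65 ± 0.31. All kept probe sets of CEP290 and ATRX, 2 and 4, are of types designed on sequence shared between transcripts, so neither gene has a value without such probe sets. TBC1D32, a ciliary protein, was at -1.25 ± 0.38, and IFT80, a subunit of the intraflagellar transport machinery, at -1.17 ± 0.31. ZEB1, a transcriptional repressor of E-cadherin, was lower by 2.60-fold (-1.38 ± 0.31), with all 3 of its probe sets lower by 1.5-fold or more. IL6ST, the signalling receptor subunit shared by interleukin-6 family cytokines, was lower by 2.42-fold (-1.27 ± 0.31) with 4 probe sets. VPS13A, a lipid transfer protein, stood at -1.37 ± 0.38, and the actin-binding NEXN at -1.39 ± 0.38. ABHD13 (-1.42 ± 0.38), ERGIC2 (-1.23 ± 0.27), PHIP (-1.23 ± 0.27) and RESF1 (-1.22 ± 0.38) completed the 12 genes. Of the genes under the floor with miR-194, ARID5A was at least 2.99-fold lower on its single probe set, and the brightest ANKRD12 probe set was at least 6.74-fold lower. That probe set is of a type that can read related sequences, the other ANKRD12 probe sets ranged up to -0.83, and without shared-sequence probe sets the log2 difference of ANKRD12 was -1.28.

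The higher genes differed by less. Only 15 genes had 2 or more probe sets that were all higher by 1.5-fold or more, against 85 genes that were lower by that rule. The rule needs a second kept probe set, which 13 of the 55 higher and 117 of the 181 lower genes past 2-fold had. HBB, a globin, was at 1.34 ± 0.38 on signals of 86.1 and 217, close to the floor and from a probe set type that can read related sequences. PPIP5K1, an inositol phosphate kinase, was at 1.18 ± 0.38, and DCBLD1 was at 1.17 ± 0.38. FGFR3, a fibroblast growth factor receptor, had the highest signals of the set, 2608 and 4395, and was higher by 1.69-fold (0.75 ± 0.27). PRKAB1, a regulatory subunit of AMP-activated kinase, was at 0.78 ± 0.31, and KHK, which phosphorylates fructose, was at 0.67 ± 0.38. The remaining genes were LOC728485 (0.73 ± 0.38), NDRG2 (0.71 ± 0.38), LINC00665 (0.71 ± 0.38), DHRS2 (0.71 ± 0.31), TSPAN18 (0.68 ± 0.38) and ZNF587 (0.66 ± 0.31). HBB, FGFR3, KHK, NDRG2 and ZNF587 were likewise read only by probe sets designed on shared sequence. NBL1 was at least 3.02-fold higher and H2AC14 at least 2.68-fold higher, both under the median floor with the control mimic. These bounds depend on that floor: with a floor at the olfactory receptor level the log2 difference of NBL1 was 1.12 and the log2 difference of H2AC14 was 0.94, which is under 2-fold. H2AC14 belongs to a family of near-identical histone genes and is uncertain for that reason.

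**Figure D1:**
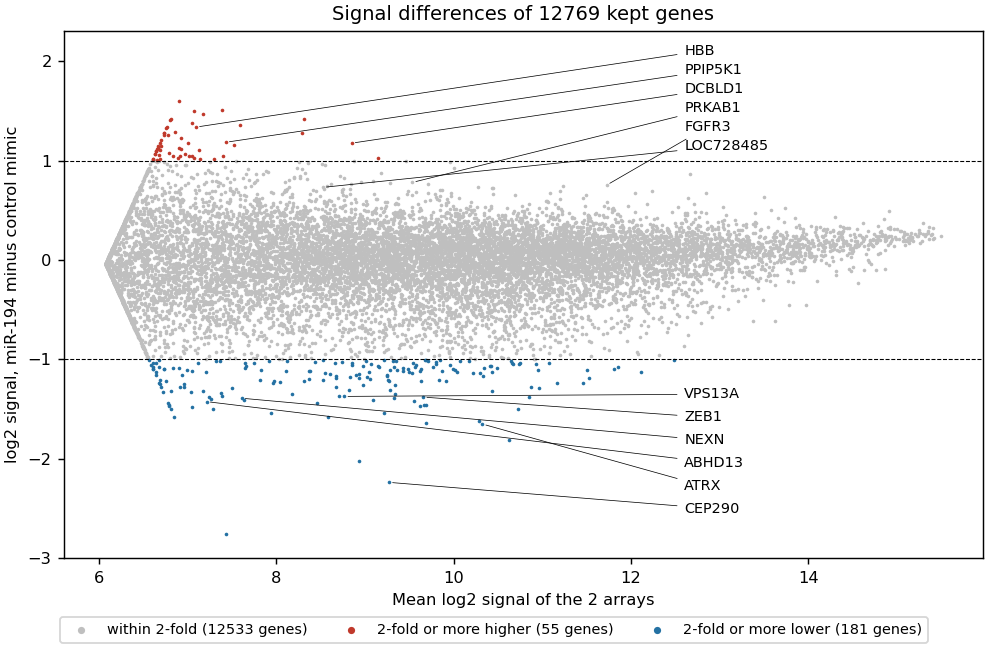
Log2 signal difference (miR-194 minus control mimic) against the mean log2 signal of the 2 arrays, 1 point per gene, with dashed lines at 2-fold. The 181 lower genes spread over most of the signal range, while the 55 higher genes lie mostly at low signal; labels give the 6 largest differences per direction among genes with agreeing probe sets and signals above the floor on both arrays, and the lowest point, at -2.75, is the bound for 1 ANKRD12 probe set.

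A second probe set of the same gene shared the direction more often for lower than for higher genes. Of the 181 lower genes, 117 had a next-brightest kept probe set, and it was also below 0 for 99 (84.6%), against 46.3% of all second probe sets. It was lower by 1.5-fold or more for 48 of the 117 (41.0%), against 8.1% of all second probe sets. Of the 55 higher genes, 13 had such a probe set, and it was above 0 for 7 (53.8%), against 53.7% of all second probe sets. It was higher by 1.5-fold or more for 3 of the 13 (23.1%), against 6.7% of all second probe sets. The share of lower genes went with gene length, a comparison added after the data were seen. Genes were put in 5 classes of genomic length. In the shortest class (median 4.50 kb), 12 of 2551 genes (0.47%) were lower by 2-fold or more. In the longest class (median 160.1 kb) 84 of 2551 genes (3.29%) were lower. Higher genes went the other way, from 18 (0.71%) to 5 (0.20%). Across genes, Spearman's rho between length and log2 difference was -0.22.

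**Figure D2:**
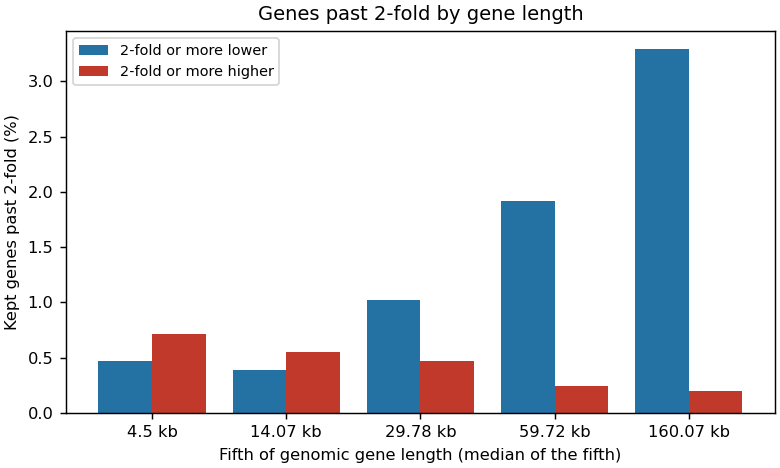
Percent of kept genes lower (blue) or higher (red) by 2-fold or more, in 5 classes of genomic gene length, with each class's median length on the x axis. The lower share is 0.47% in the shortest class and 3.29% in the longest, while the higher share goes from 0.71% to 0.20%.

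Genes that other studies have reported as miR-194 targets were lower as a list. Of 24 kept members, 16 were below 0, 5 were lower by 1.5-fold or more and 0 were higher by that size. Their median log2 difference was -0.17, and 60 of 10000 signal-matched random lists had a median as low (percentile 0.60, random lists' median 0.03, SD 0.07). FZD6, a WNT receptor, was lower by 2.11-fold (-1.08 ± 0.31) on its single probe set. PTPN13, a tyrosine phosphatase, was at -0.93 ± 0.31, but its second probe set was at -0.01. ACVR2B, an activin receptor, was at -0.83 ± 0.31 with another probe set at -0.19, and HBEGF, an EGF receptor ligand, was at -0.64 ± 0.38 with another at -0.16. SOX5 was at -0.75 ± 0.38, also on a single probe set. The highest members were TRAF6 at 0.27 ± 0.38 and RHEB at 0.26 ± 0.27, both within their error and each with another probe set below 0. With random lists matched also on gene length the percentile was 3.19, and without probe sets of shared sequence it was 5.90, both outside the lowest 2.5%.

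Of the 32 fixed lists, 1 (the reported targets) lay below and 3 lay above the central 95% of their matched random lists, where 1.6 would be outside by chance. Glycolysis and hypoxia genes were higher together: 24 of 26 were above 0, 2 passed 1.5-fold, the median was 0.24, and 0 of 10000 random lists reached it. The median of glycolysis and hypoxia was smaller after quantile normalization (0.15, percentile 99.7) and loess (0.15, percentile 99.5). Among them, ENO2, an enolase, was at 0.74 ± 0.38 on its single probe set, with signals of 74.1 and 123, close to the floor. PKM, pyruvate kinase, was at 0.73 ± 0.31, though the second PKM probe set was at -0.37. HK2, a hexokinase, was at -0.17 ± 0.27 with another probe set at 0.57, and the glucose transporter SLC2A3 at -0.15 ± 0.38. The 33 kept genes of the 47 in the ribosomal protein list were above 0 by 0.17 to 0.44 with a median of 0.23, but the median was -0.0029 (percentile 41.9) after quantile normalization and 0.05 (percentile 92.5) after loess. RPL34 was at 0.32 ± 0.27, and RPLP2, the highest, was at 0.44 ± 0.38 with another probe set at -0.56. The bacterial hybridisation spikes, control transcripts added to the labelled sample, were higher by a median of 0.18 on the same scaling. RAS, MAPK and immediate early genes had a median of 0.17 at percentile 97.7, with 4 of 18 higher and 1 lower by 1.5-fold. DUSP5, a MAP kinase phosphatase, was at 0.79 ± 0.38 and SPRED2 at 0.69 ± 0.38, while SPRED1, also a negative regulator of this pathway, was at -0.71 ± 0.38 and MAPK3 at -0.26 ± 0.31. This list was inside the central 95% under 4 of 12 alternatives, among them matching on gene length, at percentile 95.5.

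**Figure D3:**
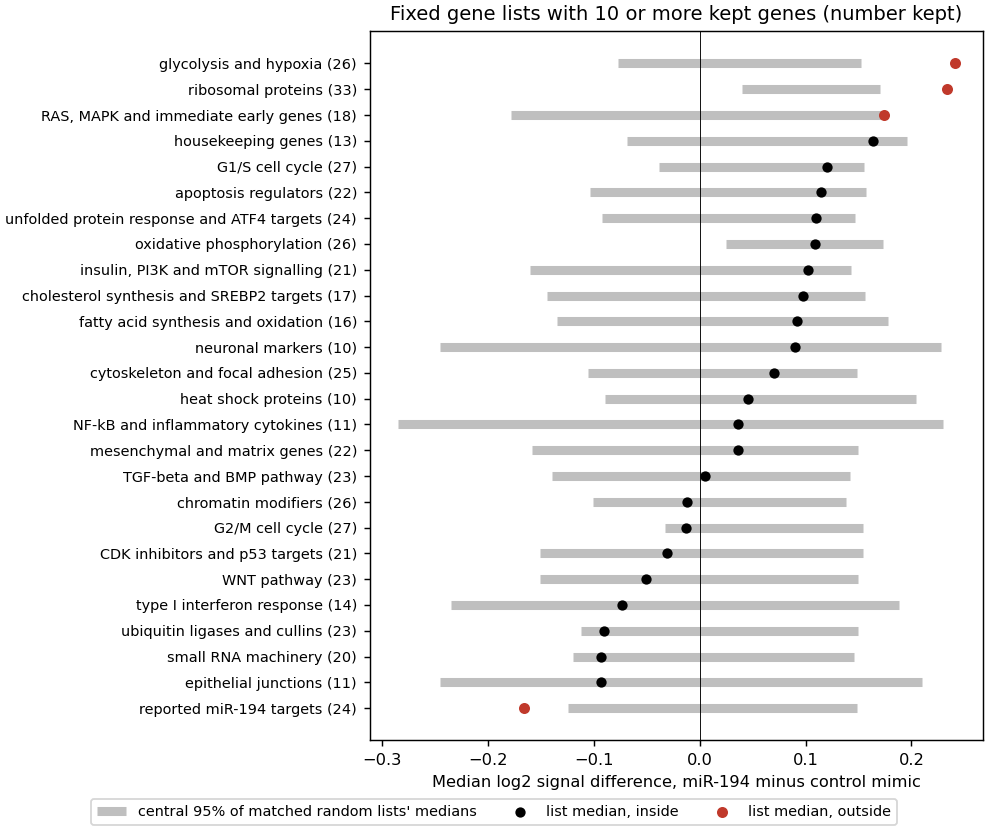
Median log2 difference (miR-194 minus control mimic) of each fixed list with 10 or more kept genes, as a point, over the central 95% of the medians of 10000 signal-matched random lists, as a grey bar; the number of kept genes follows each name. The reported targets lie below their bar at -0.17, and glycolysis and hypoxia (0.24), ribosomal proteins (0.23, but -0.0029 after quantile normalization) and RAS, MAPK and immediate early genes (0.17) lie above theirs.

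On the authors' scaling, the cell cycle lists stayed inside the range of their signal-matched random lists. Of 27 genes of mitosis, 5 were lower and 0 higher by 1.5-fold (median -0.01, percentile 5.20). The median of G2/M cell cycle was at percentile 2.46 with the gene length trend removed, and it was 0.06 at percentile 41.8 with the mean over probe sets. The kinetochore motor CENPE was lower by 3.52-fold (-1.81 ± 0.31) on its single probe set. CENPF was at -1.19 ± 0.27, while another of its 3 probe sets was at 0.45. TPX2 (0.48 ± 0.27) and KIF20A (0.30 ± 0.27) were the highest. Of 27 genes of replication and S-phase entry, E2F1 alone passed 1.5-fold (-0.67 ± 0.38), and its other probe set was at -0.10. In that list CDK6 was at -0.56 ± 0.31 with another probe set at 0.05. CDC6 (0.41 ± 0.27) and E2F2 (0.34 ± 0.31, with another probe set at -0.02) were its highest members (median 0.12, percentile 87.4). In the list of CDK inhibitors and p53 targets, RRM2B, a ribonucleotide reductase subunit, was lower by 2.04-fold (-1.03 ± 0.31), PLK3 was at -0.50 ± 0.38, and ZMAT3 (0.36 ± 0.31) and PMAIP1 (0.35 ± 0.27) were highest (median -0.03, percentile 24.3). Other probe sets reached -0.47 for ZMAT3 and -0.02 for PMAIP1. None of 22 apoptosis regulators passed 1.5-fold. CASP6 (0.53 ± 0.31) and BMF (0.48 ± 0.38) were highest and BIRC2 (-0.48 ± 0.27) and BCL2 (-0.27 ± 0.38) lowest, with a median of 0.11 at percentile 88.1. The median of apoptosis regulators left the central 95% after loess (percentile 98.4), after quantile normalization (97.9) and with the mean over probe sets (98.2).

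Stress and innate immune lists stayed inside the range of their random lists on the authors' scaling. Of 14 kept interferon-response genes, IFIT3 alone passed 1.5-fold, at least 1.58-fold lower and under the median floor with miR-194. With a floor at the olfactory receptor level the log2 difference of IFIT3 was -0.39. IFITM1 was at -0.41 ± 0.38, and ISG15 (0.39 ± 0.38) and HERC5 (0.31 ± 0.31) were highest (median -0.07, percentile 28.6). No NF-kB or cytokine gene of 11 passed 1.5-fold (median 0.04, percentile 66.6, but 0.34 at percentile 98.8 without probe sets of shared sequence). In that list IRF1 was at 0.47 ± 0.38 and ICAM1 at -0.33 ± 0.38 with another probe set at 0.43, while NFKB2 and IL1B lay under the floor on 1 array. Of 24 unfolded protein response and ATF4 target genes, ASNS, asparagine synthetase, was higher by 1.55-fold (0.63 ± 0.27) and the cystine transporter SLC7A11 was lower by 1.84-fold (-0.88 ± 0.31). The chaperone HSPA5 was at 0.53 ± 0.27 and SEL1L at -0.17 ± 0.31, and the list's median was 0.11 at percentile 89.7. Another probe set was at -0.61 for HSPA5 and at 0.01 for SLC7A11. None of 10 heat shock protein genes passed 1.5-fold on its brightest probe set, from HSPA4L (-0.29 ± 0.31) and HSPH1 (-0.05 ± 0.27) to HSPD1 (0.22 ± 0.27) and HSP90AB1 (0.31 ± 0.27), with a median of 0.05 at percentile 30.8. Other probe sets reached -0.97 for HSPA4L, ranged from -0.53 to 0.77 for HSPH1 and ranged from -0.23 to 0.62 for HSPD1.

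Metabolic lists other than glycolysis lay inside their random ranges. Among 17 cholesterol synthesis genes, TM7SF2 was at 0.82 ± 0.38, LSS at 0.45 ± 0.31, the sterol carrier STARD4 at -0.74 ± 0.31 and HMGCS1 at -0.30 ± 0.27 with another probe set at 0.75 (median 0.10, percentile 84.9). Among 16 fatty acid genes, PPARA was at 0.80 ± 0.38 with other probe sets down to -0.33, SREBF1 at 0.48 ± 0.38 with another at -0.02, ACADM, which oxidises medium-chain fatty acids, at -0.72 ± 0.27 and FADS2 at -0.52 ± 0.38 (median 0.09, percentile 76.2). None of 26 respiratory chain genes passed 1.5-fold on its brightest probe set, between NDUFB3 at -0.23 ± 0.27 and ATP5F1B at 0.31 ± 0.27, with UQCRB at -0.09 ± 0.27 and SDHC at 0.29 ± 0.27 (median 0.11, percentile 56.0). Other probe sets reached -0.64 for SDHC and 0.10 for UQCRB.

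RICTOR, a subunit of mTOR complex 2, was lower by 2.15-fold (-1.10 ± 0.31) and the S6 kinase RPS6KB1 was at -0.66 ± 0.27, while INSR (0.49 ± 0.31) and MTOR (0.41 ± 0.38) were highest in the insulin and mTOR list (median 0.10, percentile 90.9, or 97.8 with gene length matched). In the TGF-beta and BMP list, 4 of 23 genes were lower by 1.5-fold, among them SKIL, a SMAD co-repressor (-1.10 ± 0.31), and ACVR2B, while ID3 was at 0.30 ± 0.27 and TGFB1 lay under the floor on 1 array (median 0.01, percentile 42.1). In the WNT list FZD3 was at -0.80 ± 0.38 beside FZD6, and RNF43 (0.50 ± 0.38) and MYC (0.45 ± 0.27) were highest (median -0.05, percentile 19.4). Of 25 cytoskeleton and focal adhesion genes, the integrin ITGAV was lower by 2.03-fold (-1.02 ± 0.31) and the kinase ROCK2 was at -0.91 ± 0.31, while RHOA (0.43 ± 0.27) and ACTB (0.42 ± 0.27) were highest (median 0.07, percentile 70.4). In the mesenchymal list ZEB1 and ZEB2 (-0.53 ± 0.38) were lowest, and MMP14 (0.87 ± 0.38) and FN1, fibronectin (0.77 ± 0.31), were highest, each of the latter with another probe set below 0 (median 0.04, percentile 62.3). Other probe sets of RPS6KB1 reached 0.23, those of INSR reached -0.11, and those of SKIL and ROCK2 reached -0.15. Among 11 epithelial junction genes TJP1 was at -0.68 ± 0.27 with another probe set at 0.28, DSC2 at -0.51 ± 0.38 with another at 0.06, and KRT8 at 0.11 ± 0.38 (median -0.09, percentile 18.1).

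On the authors' scaling, lists of gene regulation machinery stayed inside the central 95% of their random lists. Of 20 small RNA machinery genes, 3 were lower by 1.5-fold and 0 higher (median -0.09, percentile 5.17). XRN1, the cytoplasmic exonuclease, was at -0.86 ± 0.31 and DICER1, which cuts microRNA precursors, at -0.67 ± 0.27, with AGO3 (0.44 ± 0.38) and AGO2 (0.36 ± 0.31) highest. Of 23 ubiquitin ligase genes, NEDD4 (-0.75 ± 0.38) and CUL5 (-0.73 ± 0.27) were lower by 1.5-fold, and ITCH (0.33 ± 0.31) and TRAF6 were highest (median -0.09, percentile 4.31). Among 26 chromatin modifiers TET2 was at -0.61 ± 0.38, KDM6B at -0.55 ± 0.38, DNMT3B at 0.35 ± 0.31 and TET3 at 0.21 ± 0.31 (median -0.01, percentile 23.5). Another probe set had the opposite sign for AGO3 (-0.51), ITCH (-0.58), TET2 (0.32) and KDM6B (0.23). Other probe sets reached -0.03 for XRN1, -0.19 for DICER1 and -0.16 for CUL5.

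Markers of other cell types were mostly under the filter. The kept genes numbered 3 of 19 hepatocyte, 1 of 13 enterocyte, 7 of 13 fibroblast, 5 of 16 blood, 2 of 10 endothelial and 3 of 12 keratinocyte markers. Their percentiles were 62.9, 37.0, 59.6, 32.6, 26.9 and 9.12. The median of keratinocyte markers was at percentile 2.33 with gene length matched and at 39.5 with the mean over probe sets, and the median of endothelial markers was at percentile 99.0 with no floor. HBB and the fibulin gene FBLN1 (0.61 ± 0.38, with another probe set at -0.20) were the members past 1.5-fold. Of 16 neuronal markers 10 were kept, with a median of 0.09 at percentile 75.5, SYT1 at -0.69 ± 0.38, and SYP at least 1.56-fold higher, a bound that rests on the median floor, since the log2 difference of SYP was 0.16 with a floor at the olfactory receptor level. Of 16 housekeeping genes 13 were kept. Their median was 0.16 at percentile 91.8, with IPO8 lowest (-0.19 ± 0.27, with another probe set at 0.16) and ACTB and POLR2A (0.33 ± 0.31) highest.

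The 2 arrays differed in the signal from 5' ends of control transcripts. For beta-actin the 3' over 5' signal ratio was 4.94 with the control mimic and 2.59 with miR-194. Of the bacterial poly-A spikes, which are added to the RNA before labelling, dap had ratios of 5.90 and 2.25 and thr of 7.77 and 3.46. The phe spike had 1.40 and 1.09, and the lys spike 0.75 and 0.61. GAPDH had ratios of 1.01 and 1.03. Over these 6 transcripts the log2 difference between the arrays was larger at the 5' end than at the 3' end by a median of 0.65, from -0.03 for GAPDH to 1.39 for dap. The probe sets for 18S ribosomal RNA were higher with miR-194 by a median of 0.74, and by 0.57 to 0.72 under the other scalings. These values stand beside every gene group above, since each group is compared between the same 2 arrays.

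**Figure D4:**
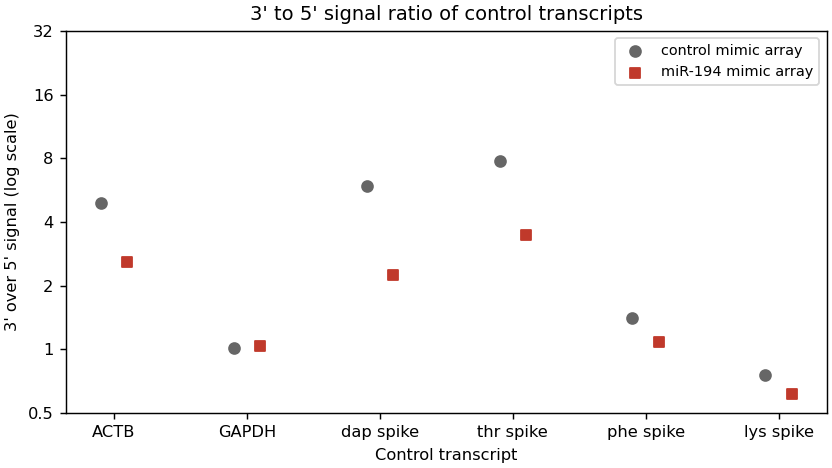
Ratio of 3' to 5' probe set signal, on a log scale, for 2 human transcripts and 4 bacterial poly-A spikes on the control mimic array (grey circles) and the miR-194 array (red squares). The ratio is lower with miR-194 for beta-actin (2.59 against 4.94), dap and thr, and about equal for GAPDH (1.03 against 1.01).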

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

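The gene length alternatives were chosen after the data were seen. The counts of genes past 2-fold depended on how low signals were treated. Against 55 higher and 181 lower genes, the counts were 592 and 906 with a floor at the 25th percentile, 1622 and 1999 with no floor and no filter, and 1 and 89 with a floor at the 75th percentile. With a floor at the olfactory receptor level 20 genes were higher (165 lower). A 1.5-fold threshold gave 381 and 933, agreement between probe sets 7 and 86, and the mean over probe sets 94 lower (47 higher). The other scalings, leaving out probe sets of shared sequence, and the gene length correction kept both counts within 1.5 times. Lower genes outnumbered higher ones under each of these settings. The reported targets' median stayed between -0.19 and -0.12 under the 10 alternatives that can change it, and below the central 95% of random lists under 10 of all 12; without shared-sequence probe sets it was at percentile 5.90 and with length matching at 3.19. Glycolysis and hypoxia stayed above it under all 12, the lowest at percentile 99.5, with a median of 0.15 after quantile normalization and after loess. The higher median of ribosomal proteins was gone after quantile normalization (-0.0029, percentile 41.9). For named genes, 1264 of 1328 alternative values lay within the probe set error of the reported one (599 of them equal to it), 63 lay farther off, and 1 changed sign for a gene reported past 1.5-fold, CENPF without shared-sequence probe sets (0.45). With smaller differences included, 24 values changed sign, 13 of them by more than the probe set error and 4 under another scaling. For the other lists, over the alternatives that can change a median, 272 of 306 medians lay within 1 SD of their random lists from the reported one (72 equal to it), and the cause of the larger moves was not tested. Setting the median of kept genes to 0 shifts every gene by the same 0.02. That shift cannot change a percentile and is below every probe set error and every random list SD. In the tallies of lists and named genes this alternative could therefore only count as unchanged. Alternatives on 3' UTR choice were not run, and no array could be left out. No paired analysis was possible because each group has 1 array. Signal over background limits the genes near the floor, where the probe set error is 0.38.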

Other observations

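The family scan, the gene length comparisons and the test on 5' ends were chosen after the results were seen; the limits of the other tests were set before their values were computed. Genes were grouped by symbol stem, and 145 stems had 10 or more kept genes. By signal-matched random lists, 7 stems lay below the central 95% and 6 above it, where 3.6 per tail would by chance. The 4 stems described here are a choice among these 13 made after the values were seen, and their directions held under the median, quantile and loess scalings. Of the others, ARHGAP, USP, CHD and LRRC were low at percentiles 0.54 to 1.28, below IFT, and PARP, COL and CYB were high at 98.9 to 99.3. With gene length matched too, ARHGAP (4.51), USP (5.6) and CHD (6.57) were inside the central 95%. LRRC stayed below it at 1.59, and PARP, COL and CYB stayed above it at 97.83 to 99.48. With length matched, ZNF (0.145), SMIM (0.29) and THAP (1.31) also lay below it and ST (98.76) above it, though inside it by signal alone. After loess USP (5.30) and LRRC (3.18) were inside it. The highest percentiles were those of RPL and RPS (99.99 and 99.96), which depended on scaling: after quantile normalization RPL was at percentile 63.6 and RPS at 28.8, with a median of -0.01. The CEP genes, most of them centrosomal proteins, had the lowest percentile: 25 of 35 were below 0, 14 were lower and 0 higher by 1.5-fold, and the median was -0.28 (percentile 0.01, and 0.10 with gene length matched too). Beside CEP290, CEP85L stood at -1.22, CEP295 at -1.11 and CEP350 at -1.06. The IFT genes of intraflagellar transport had a median of -0.18 over 18 genes (percentile 1.63), with IFT74 at -1.05. With length matched the IFT percentile was 3.65, inside the central 95%. The KIF kinesins had a median of -0.17 over 33 genes (percentile 0.57, and 2.1 with length matched), with KIF20B at -1.64. CEP85L, CEP295, CEP350, IFT74 and KIF20B were picked after the values were seen, outside the naming rule, and are given without the probe set error. KIF20B and CEP85L differ by more than IFT80 but are not among the 12 lower genes named above. They therefore fell short of the rule of agreeing probe sets above the floor. On the other side, the ALG genes, enzymes of N-glycan assembly, had a median of 0.30 over 11 genes (percentile 99.95, and 99.92 with length matched).

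Lower genes outnumbered higher genes by 3.29 at 2-fold, a ratio that the floor moved more than the scaling or gene length did, to 1.23 with no floor, 1.53 at the 25th percentile and 89.0 at the 75th. A scaling error of the kind that quantile normalization or loess removes is argued against. The smallest ratio under 3 other scalings was 2.44 (95% counting interval 1.83 to 3.25). The median scaling shifts every gene by only 0.02 and could hardly lower the ratio. None of the 3 can show an offset shared by all genes. No scaling on the hybridisation spikes, which were higher by a median of 0.18, was run. Counting intervals take the genes as independent, although all come from the same arrays, so they hold no variation between cultures, labelling reactions or arrays. The control transcripts' 5' signal, taken against their 3' signal, was higher on the miR-194 array by a median of 0.65 over 6 transcripts (-0.03 to 1.39). That is the opposite of a loss of 5' ends in the labelling of that array, but the question was chosen after the values were seen. The control mimic array had the weaker 5' signal by this median, and whether this bears on the ratio was not tested. The poly-A spikes among the 6 transcripts were added to the RNA, so they cannot show loss of 5' ends in the cells' own RNA. The human transcripts were at 0.93 (beta-actin) and -0.03 (GAPDH), too few to decide that question. The lower genes had a median length of 86.0 kb against 29.8 kb for all kept genes. Removing the trend with gene length left 124 lower and 62 higher genes, a ratio of 2.0. That is above 1.5, the limit set before the ratio was computed, though its counting interval (1.47 to 2.71) takes in 1.5. How far the ratio would vary between repeats is not known with 1 array per group, so a trend with gene length stays open. Whether gene length stands in for transcript length, base composition or 3' UTR sites was not tested, and a labelling difference and an effect of the mimic remain possible, because mimic, culture and array cannot be told apart with 1 array per group.

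The reported targets' lower median may reflect silencing by the mimic, which is a hypothesis. Without its 2 lowest members, FZD6 and PTPN13, the percentile was 0.96 (median -0.16). A median moves little when its lowest members are left out, so this check could hardly fail and decides nothing. A trend with gene length cannot be excluded: the gap to the random lists' median went from -0.19 (SD 0.07) to -0.15 (SD 0.07) when length was matched, at percentile 3.19, while removing the length trend left percentile 1.38. The list was assembled from general knowledge of the literature, and pairing with 3' UTR sites was not tested.

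Glycolysis and hypoxia genes were higher by a small amount that gene length did not account for, since with length matched the percentile was 100 (0 of 10000 random lists as high). Without ENO2 and PKM, the highest members, the percentile was 99.98. A median moves little when its highest members are left out, so this check could hardly fail and decides nothing. A difference in culture density or oxygen between the dishes, a labelling difference and an effect of the mimic all stay open and untested.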
